A study of Homo sapiens with 6 samples.

How the data were processed

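RNA sequencing was done on 3 human cutaneous melanoma cell lines, 1205Lu, WM983B and WM1341D, each as 1 culture stably expressing bone morphogenetic protein 6 (BMP6) and 1 corresponding control culture, which gave 6 libraries. The labels give the genotype BRAFV600E for all 6 libraries. For the control they state wild type and name no vector control. Effects of making a stable culture thus cannot be told apart from those of BMP6. Per the labels, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name bcl2fastq, Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2, and the genome build hg19. The annotation release, the strand setting and any filter are not given in the sources used here.

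For each cell line the authors made 1 table of raw counts per Ensembl gene and 1 table of TPM (transcript abundance scaled for gene length and library size), with 1 column per library. The deposited counts are whole numbers without scaling. The deposited TPM values sum to the same total in every library and were made from the same counts with 1 fixed length per gene, since counts divided by TPM gave the same relative length in every library, with a largest deviation of 2.17e-04 on the log2 scale. The 3 count tables were joined by gene identifier. Of 57500 identifiers, 55082 were found in a table of gene names and 40373 of them carried a symbol. Coordinates were taken from GENCODE release 44 mapped to GRCh37, the assembly known as hg19.

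Total counts were 24526277 for the library labelled 1205Lu BMP6, 25867398 for the 1205Lu control, 31971901 and 30248281 for WM983B BMP6 and control, and 29060384 and 31341943 for WM1341D BMP6 and control. A count of 0 allows up to 3 counts, which is between 0.0938 and 0.122 CPM (counts scaled to library size) in these libraries. Counting intervals and these floors cover counting error only, since reads amplified by PCR are not independent molecules.

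The comparison of BMP6 with control across the 3 cell lines used edgeR 4.0.16 in R 4.3.3 on the counts, with filterByExpr, TMM scaling, a cell-line term that pairs each BMP6 library with its control, and the robust quasi-likelihood test. This leaves n = 3 pairs and 2 residual degrees of freedom. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F. That F borrows its spread from other genes, so the SE is not the plain SE over the pairs. P-values were adjusted by the Benjamini-Hochberg method over 17918 tested genes, with a threshold of 0.05. Gene lists were tested with the two-sided camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01, adjusted over the 32 lists with at least 5 tested members. With that preset value the p-value rests on the spread between genes. It does not measure how far a list varies between cultures. The lists held 784 entries, of which 781 were matched and 671 tested. SOD2, BAGE and PECAM1 were not matched, and SOX10 was listed at 0 in every library, which need not reflect its expression, since reads shared with an overlapping gene can be left uncounted.

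Within a cell line there was 1 library per condition and so no test. Changes are log2 ratios of TMM-scaled CPM with a prior count of 2. A gene counted as different by size where the ratio was at least 2-fold and the higher library reached 5 CPM. Each fold of a named gene has a 95% exact binomial counting interval. The median log2 ratio of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins. The members of a random list need not vary together. Its range thus leaves out variation that genes regulated together share between single cultures, and a median outside it is no test of BMP6. Pairs of cell lines were compared by Pearson and Spearman correlations of the log2 ratios across genes and by the overlap of genes past the size rule. Genes are not independent replicates, so these have no p-value.

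The tests, the lists, the size rule and the rule for naming genes were fixed before the data were examined. The rule names BMP6, the 4 members with the largest absolute log2 fold change of each of the 3 BMP lists, and 12 genes per direction across the cell lines. Where fewer than 12 passed the test, it takes genes that reached 5 CPM in every line and moved the same way in all 3, ranked by the smallest of the 3 ratios. It also names the 6 genes with the largest ratio per direction within each line, and the 3 members with the largest absolute log2 fold change of each other list that passed camera or lay outside its random lists. Some genes that the rule selects are not analysed here, so a list or line may show fewer. Genes of the Y chromosome, XIST and TSIX were left out of the named genes, the plots and the table of all genes.

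The alternatives were no cell-line term, size factors of DESeq2 (RLE), scaling to library size, DESeq2 1.42.0, limma-voom, no filter on low counts, 1 CPM in 3 libraries, limma on log2 of TPM plus 1 or plus 0.1, and leaving out each pair. For lists they were an estimated correlation and fry. Within cell lines they were a prior count of 0.5, minima of 1 CPM or none, and ratios of TPM plus 1. Because the library labelled 1205Lu BMP6 stood apart from its control, DESeq2, limma-voom and camera with an estimated correlation were also run on the WM983B and WM1341D pairs alone. Those 3 runs were chosen after the data were seen. Samples were never regrouped by their expression.

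The gene test was tested on simulated data of the same design. Each changed gene had a mean count above 50 and the same fold in every line, and the spread followed expression level alone. With the spread fitted to the 3 pairs, over 17430 genes, it recovered 3 of 50 genes changed 2-fold, 39 of 50 changed 4-fold, 46 of 50 changed 8-fold and 50 of 50 changed 64-fold, with 3 false calls. With the spread of the WM983B and WM1341D pairs, over 16871 genes, it recovered 40, 49, 50 and 50 of 50, with 5 false calls. Recovery of changes that differ between lines was not simulated. BMP6, with a log2 fold change of 6.37 that differed between lines, did not pass on 3 pairs. In a single simulated data set of the WM983B and WM1341D pairs without a change, camera called 0 of 30 lists. Genes were drawn independently there, so this cannot show how camera treats lists whose members vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.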

Results

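The series holds gene counts from 6 RNA-seq libraries, 1 BMP6 and 1 control library for each of the human melanoma lines 1205Lu, WM983B and WM1341D. BMP6 is a secreted ligand of the TGF-beta superfamily that signals through SMAD proteins. The design sets each line that overexpresses BMP6 against its own wild type control, so the question is which transcripts differ when BMP6 is stably expressed. Total counts ranged from 24526277 for the library labelled 1205Lu BMP6 to 31971901 for WM983B BMP6. No cell line has replicate libraries of 1 condition, and the 3 lines serve as the replicates of the comparison across lines.

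The library labelled 1205Lu BMP6 differed widely from the 1205Lu control. BIRC7, an inhibitor of apoptosis found in melanoma, had 3886 counts in the former and 4 in the latter, and the WM983B BMP6 library had 3186. The transcription factor SOX9 had 10 counts against 16059 in the 1205Lu control, and WM983B BMP6 had 12. Across genes, the Pearson correlation of log2 CPM of the library labelled 1205Lu BMP6 was 0.991 with WM983B BMP6, 0.981 with the WM983B control and 0.854 with the 1205Lu control. The corresponding value was 0.984 for the WM983B pair and 0.990 for the WM1341D pair. All values for 1205Lu below carry this difference, and values without the 1205Lu pair follow in parentheses or beside those with it where they could be had.

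**Figure D1:**
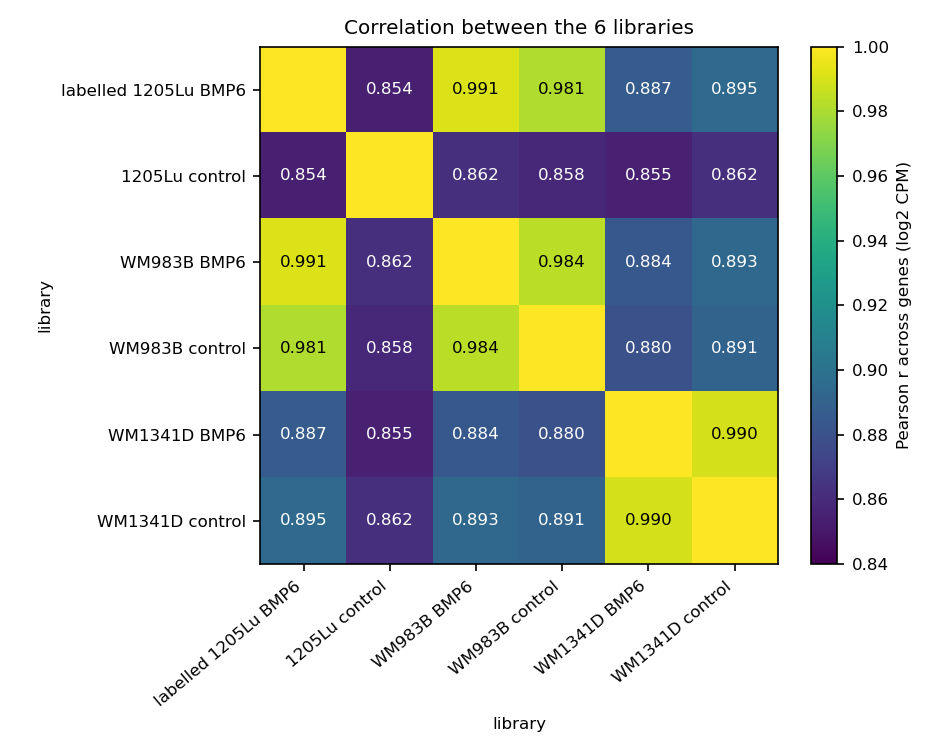
Pearson correlation across genes of log2 CPM for each pair of the 6 libraries, 1 square per pair with its value. The library labelled 1205Lu BMP6 lies at 0.991 with WM983B BMP6 and at 0.854 with the 1205Lu control.

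BMP6 itself (ENSG00000153162, chromosome 6, 7726332 to 7881961, plus strand, GRCh37) was higher in the BMP6 library of all 3 lines. WM983B had 140 CPM (4795 counts) against 0.464 CPM (15 counts) in its control, a 301-fold difference with a counting interval of 182 to 538. WM1341D had 160 CPM (4257 counts) against 0.778 CPM (23 counts), a 205-fold difference with an interval of 137 to 324. The library labelled 1205Lu BMP6 had 89.3 CPM (2352 counts) against 14.1 CPM (339 counts), which is 6.34-fold with an interval of 5.66 to 7.13. The log2 fold change across the lines was 6.37 ± 1.64 (SE, n = 3 pairs), with an adjusted p of 0.910 in edgeR. In the WM983B and WM1341D pairs alone BMP6 rose by 7.92 ± 0.21 on the log2 scale (SE, n = 2 pairs), with an adjusted p of 3.43e-05.

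Several genes had the same direction in all 3 lines without passing the edgeR test. DSP (ENSG00000096696, chromosome 6, 7541571 to 7586947), which encodes the desmosome protein desmoplakin, had 2.80 CPM in WM983B BMP6 against 10.0 in its control and 12.7 in WM1341D BMP6 against 35.8. Its log2 fold change was −2.06 ± 0.36 (−1.66 without the 1205Lu pair). NIBAN1 (ENSG00000135842, chromosome 1, 184759858 to 184943640) had a log2 fold change of −1.26 ± 0.17 (−1.14), with 27.4 against 64.1 CPM in WM983B and 23.1 against 47.8 in WM1341D. TRAF1 (ENSG00000056558), an adaptor of TNF receptor signalling, had −1.01 ± 0.15 (−0.92), and MYEOV (ENSG00000172927) had −1.60 ± 0.25 (−1.43). SCD (ENSG00000099194, chromosome 10, 102106990 to 102124583), the desaturase that makes oleate, had 843 against 533 CPM in WM983B and 1701 against 1215 in WM1341D, with a log2 fold change of 0.67 ± 0.16 (0.57).

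The other genes that the naming rule selected on the higher side were OLFML2A, GNG7, BCYRN1, INKA2, MTSS2, MOCOS, TSPAN7, HHLA3, FABP7, HES6 and ELOVL2. Their smallest within-line log2 ratios ran from 0.46 for ELOVL2 to 0.96 for OLFML2A. OLFML2A had log2 ratios of 4.42, 3.33 and 0.96 in 1205Lu, WM983B and WM1341D, and GNG7, a G protein gamma subunit, had 0.95, 0.68 and 0.68. The fatty acid carrier FABP7 had 6.72, 0.51 and 0.76. On the lower side they were NID1, BAALC, EMILIN1, SYT11, ZC3HAV1L, FGF13, CARD10 and APH1B. The matrix protein genes NID1 and EMILIN1 had log2 ratios of −3.18, −0.93 and −1.04, and of −3.59, −0.81 and −1.62.

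Over the 17918 genes, edgeR called 0 higher and 0 lower, with a lowest adjusted p of 0.910. At an unadjusted p under 0.05 there were 76 higher and 136 lower, together 212, which is below the share of 0.05 that chance gives. Of the other methods, limma-voom also called 0 and 0, and DESeq2 called 3 higher and 15 lower. The DESeq2 genes were BMP6, CCDC144NL-AS1 and OLFML2A on the higher side, and THNSL2, NIBAN1, CDCA7L, PHETA2, DSP, MYEOV, TRAF1, RTL8B, GATA4, SLC9B2, MT1E, TENM1, FLT1, HRH1 and DPY19L2P2 on the lower side. In the WM983B and WM1341D pairs alone edgeR called 1 gene higher, which was BMP6, and 0 lower. Of 17258 genes tested there, 290 and 455 had an unadjusted p under 0.05, together also below that share. DESeq2 called 8 and 20 there, among them SCD higher (log2 fold change 0.57, adjusted p = 0.0247) and DSP, NIBAN1, TRAF1 and MYEOV lower, and 9 genes were shared with its calls on 3 pairs. Of the 17918 genes, 4665 (26.0%) had the same direction in all 3 lines, where chance gives 25%.

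**Figure D2:**
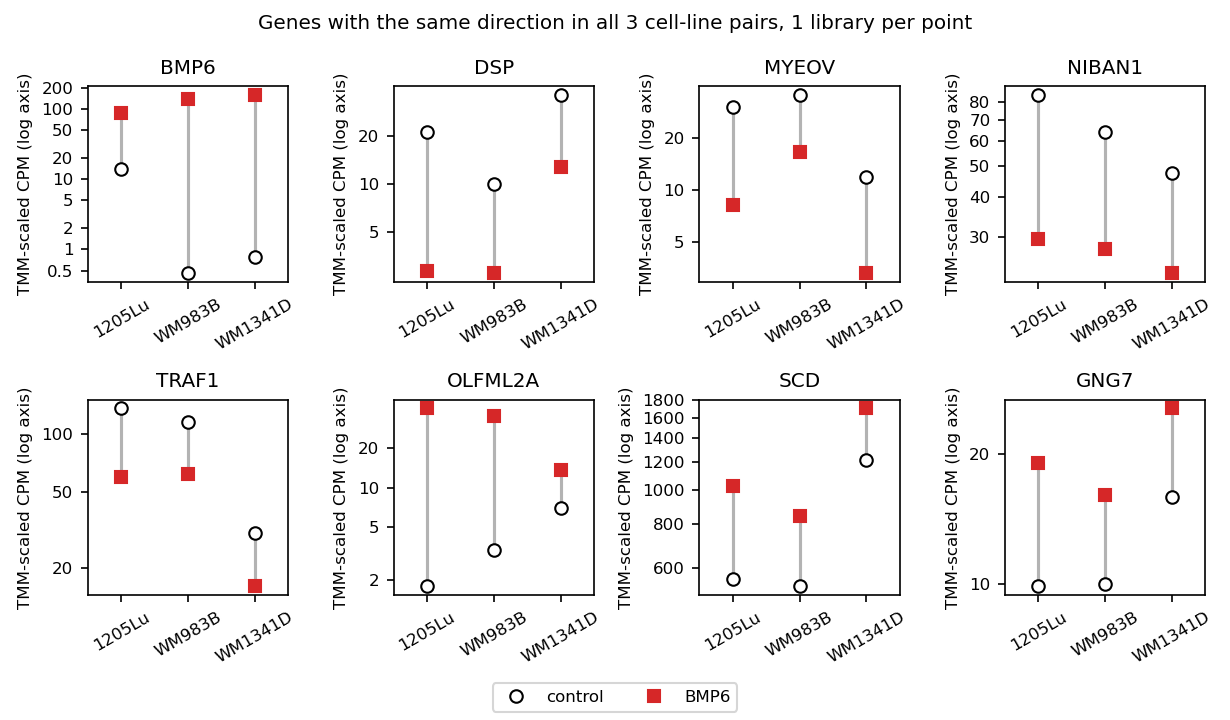
TMM-scaled CPM on log axes of 8 genes with the same direction in all 3 cell lines, for control (open circles) and BMP6 libraries (red squares), 1 library per point. BMP6 reaches 140 CPM in WM983B and 160 CPM in WM1341D, and DSP is lower in the BMP6 library of every line.

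Mitotic genes were lower in the BMP6 libraries as a group. Of 42 G2/M genes tested, 28 were lower in all 3 lines and 0 higher in all 3, and 34 were lower in both WM lines. The median log2 ratio was −0.47 in 1205Lu, −0.27 in WM983B and −0.10 in WM1341D, each below the central 95% of matched random lists. Random lists leave out variation that such genes share between single cultures. The kinetochore motor CENPE had log2 ratios of −0.94, −0.71 and −0.30, HMMR had −0.91, −0.83 and −0.16, and CKAP2 had −1.07, −0.64 and −0.13. The list fell by camera with an adjusted p of 4.04e-07 on 3 pairs and 1.29e-08 on the WM983B and WM1341D pairs, and had an adjusted p of 0.613 and 0.820 with an estimated correlation. The 45 G1/S genes did not pass, with an adjusted p of 0.196 (0.0780 without the 1205Lu pair) and medians of 0.13, 0.06 and 0.05. The 26 cell cycle inhibitors and p53 targets did not pass either (adjusted p = 0.136, and 0.117 without the 1205Lu pair, medians −0.46, −0.09 and −0.05). CDKN1C, CDKN2A and CDKN1A had the largest log2 fold changes in them, of −1.89, 1.45 and −1.13, but −0.31, −0.24 and −0.01 without the 1205Lu pair, so the direction of CDKN2A turned.

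Cholesterol synthesis genes were higher as a group. Of 24 tested, 13 were higher in all 3 lines and 1 lower, and 15 were higher and 1 lower in both WM lines. The medians were 0.71, 0.25 and 0.23, each above the central 95% of random lists. The same limit of random lists holds here. INSIG1, which retains the SCAP-SREBP complex in the endoplasmic reticulum, had log2 ratios of 1.71, 0.74 and 0.39, and squalene epoxidase (SQLE) had 1.41, 0.38 and 0.30. The list rose by camera with an adjusted p of 4.95e-06 on 3 pairs and 2.43e-07 without the 1205Lu pair, and had an adjusted p of 0.613 and 0.820 with an estimated correlation.

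Transcriptional targets of BMP signalling were not higher as a group where BMP6 was expressed. Of 23 BMP target genes tested, 0 were higher in all 3 lines and 3 were lower, and the medians of −0.07 in WM983B and −0.03 in WM1341D lay inside the range of random lists. ID1, a direct SMAD target that was chosen here after its values were seen, had 1548 against 1565 counts in WM983B, 177 against 172 in WM1341D and 1027 against 2204 in 1205Lu. The 4 members with the largest log2 fold changes were MSX2 (−1.69 ± 1.96), GATA2 (−1.44 ± 0.66) and ID4 (1.04 ± 0.80), and GATA3, which had log2 ratios of −2.80, −0.51 and 0.40 in 1205Lu, WM983B and WM1341D. Without the 1205Lu pair the 4 had 0.36, −0.46, 0.09 and 0.06, so MSX2 and GATA3 turned. The list fell by camera on 3 pairs with an adjusted p of 0.0159, where the 1205Lu median was −1.09, and had an adjusted p of 0.613 with an estimated correlation and 0.794 without the 1205Lu pair.

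The 21 BMP ligands, receptors and transducers did not pass (adjusted p = 0.745, and 0.606 without the 1205Lu pair), with medians of −0.18, −0.04 and −0.12, of which the last lay below the random lists. GDF7, BMP8A, INHBA and BMP7 had the largest log2 fold changes, of 2.07, 1.28, −1.20 and −1.10 (−0.45, 0.87, −0.37 and 1.06 without the 1205Lu pair). The 7 secreted BMP antagonists did not pass (adjusted p = 0.0587, and 0.613 with an estimated correlation), with medians of −1.51, 0.06 and 0.05. They passed as lower with scaling to library size (adjusted p = 0.0356) and without the WM1341D pair (0.0102), and turned to higher without the 1205Lu pair (0.461). Over all alternatives their adjusted p ran from 0.0102 to 0.820. BMPER, CHRD, FSTL1 and FSTL3 led that list, with log2 fold changes of −3.54, −1.92, −0.80 and −0.68 (0.24 and −0.34 for the last 2 without the 1205Lu pair, where BMPER and CHRD were not tested), and CHRD had 0 counts in both WM1341D libraries. The 11 osteogenic genes (adjusted p = 0.0587, and 0.313 without the 1205Lu pair, medians −1.43, −0.05 and 0.06) were led by PHEX, MSX2 and SPP1, with log2 fold changes of −2.14, −1.69 and 1.36, of which MSX2 and SPP1 turned to 0.36 and −0.30 without the 1205Lu pair, where PHEX was not tested.

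Differentiation and matrix genes moved mainly in the 1205Lu pair, whose BMP6 library stood apart from its control. The 29 melanocyte differentiation genes rose by camera (adjusted p = 1.18e-06, and 0.613 with an estimated correlation), with a median of 5.29 in 1205Lu but −0.23 in WM983B and −0.04 in WM1341D. GPR143, SLC45A2 and PPARGC1A had log2 ratios of 8.90, 8.84 and 5.29 in 1205Lu, and of 0.26, −0.42 and −0.27 in WM983B. Without the 1205Lu pair the same list fell, with an adjusted p of 0.0119, and 0.820 with an estimated correlation. The 25 dedifferentiated, AXL-type genes fell (adjusted p = 0.00938, and 0.613 with an estimated correlation), with medians of −2.09, 0.46 and −0.19. F2RL1, PDGFRB and EPHA2 had log2 fold changes of −2.09, −1.73 and −1.59 there (−0.36, −0.16 and −0.43 without the 1205Lu pair), and the list had an adjusted p of 0.313 without the 1205Lu pair.

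The 32 epithelial-mesenchymal and matrix genes (adjusted p = 4.79e-04, medians −1.38, −0.01 and 0.03) and the 17 TGF-beta target genes (adjusted p = 0.00206, medians −1.08, 0.01 and −0.07) also fell by camera on 3 pairs. Each had an adjusted p of 0.613 with an estimated correlation, and of 0.548 and 0.982 without the 1205Lu pair. ZEB1, COL6A3 and COL5A1 led the matrix list with log2 fold changes of −2.05, −1.86 and −1.77 (0.10, −0.57 and −0.33 without the 1205Lu pair), and ANGPTL4 and TGFB1 had −1.59 and −1.47 in the TGF-beta list (−0.37 and −0.20). The 13 mitochondrially encoded genes rose (adjusted p = 0.0159, 0.613 with an estimated correlation, 0.111 without the 1205Lu pair and 0.217 without the WM1341D pair). MT-CO1, MT-ND4 and MT-CO2 had the largest log2 fold changes there, of 0.39, 0.35 and 0.33 (0.11, 0.17 and 0.24), and the share of mitochondrially encoded counts was 6.92% in the library labelled 1205Lu BMP6 against 3.99% in its control.

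Among markers of other cell types, 5 keratinocyte markers fell by camera (adjusted p = 0.00153, and 0.613 with an estimated correlation), led by KRT15, DSP and PERP with log2 fold changes of −2.11, −2.06 and −0.51 (−1.12, −1.66 and 0.09 without the 1205Lu pair). Without the 1205Lu pair that list had an adjusted p of 1.15e-04, and 0.820 with an estimated correlation, and DSP had log2 ratios of −1.82 and −1.49 in WM983B and WM1341D. The 5 endothelial markers fell with an adjusted p of 0.0492, and 0.613 with an estimated correlation and 0.0516 with RLE size factors. They had 5 tested members only with all pairs and the cell-line term, or without the WM983B pair, where the adjusted p was 0.0422. CLDN5, ERG and EGFL7 led them with log2 fold changes of −1.78, −1.29 and −0.40 (ERG −0.80 and EGFL7 0.20 without the 1205Lu pair), and CLDN5 had 20 counts or fewer in every library. The 12 fibroblast markers (adjusted p = 0.136, and 0.588 without the 1205Lu pair; PDGFRA, PRRX1 and PDGFRB at −2.09, −1.83 and −1.73, and −0.06, −0.81 and −0.16 without the 1205Lu pair) and the 5 leukocyte markers (adjusted p = 0.804) did not pass.

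The remaining lists did not pass camera on 3 pairs, and several lay outside their random lists in single lines. Interferon response genes (35 tested, adjusted p = 0.0761) were lower in WM983B and WM1341D, with medians of −0.23 and −0.17, and fell in those pairs alone with an adjusted p of 1.09e-04, and 0.820 with an estimated correlation. OASL, RSAD2 and IFI27 had the largest log2 fold changes of the list, −2.50, −2.11 and −2.10 (−1.02 for IFI27 without the 1205Lu pair, where OASL and RSAD2 were not tested). The 20 cytokines and chemokines tested in those pairs (adjusted p = 0.0174), 24 ERK pathway output genes (0.0195), 22 YAP and TEAD target genes (0.0316) and 16 immediate early and heat shock genes (0.00130) rose there, each with an adjusted p of 0.820 with an estimated correlation. Their medians were 0.31, 0.27, 0.56 and 0.49 in WM983B, but −0.06, 0.02, −0.17 and 0.02 in WM1341D. They lay above their random lists in WM983B, and in WM1341D inside them for all but the YAP and TEAD targets, which lay below. On 3 pairs their adjusted p was 0.328, 0.359, 0.532 and 0.804. The chemokines CCL2 and CXCL8 had log2 ratios of 2.01 and 1.98 in WM983B, at 4102 against 959 counts and 8188 against 1951, and IL11 had the next largest log2 fold change of its list, −1.59 (0.17 without the 1205Lu pair).

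In the same lists EPHA4, EPHA2 and EGR2 led the ERK output genes with log2 fold changes of −2.18, −1.59 and −1.39 (0.11, −0.43 and 0.24 without the 1205Lu pair). IGFBP3, AXL and FJX1 led the YAP and TEAD targets with −2.05, −1.43 and −0.99 (−0.66, 0.02 and −0.08), and HSPA1B, DUSP1 and NR4A1 led the immediate early and heat shock genes with 1.02, −0.95 and 0.93 (0.46, −0.11 and 0.03). NF-kB target genes (18 tested, adjusted p = 0.193, and 0.656 without the 1205Lu pair) had medians of 1.32, 0.13 and −0.17, and CXCL8, TNFAIP2 and CXCL1 led them with 2.64, −2.06 and 1.49 (1.55, −0.64 and 0.00). Antigen presentation genes (23, adjusted p = 0.441, and 0.111 without the 1205Lu pair) had medians of 0.51, −0.16 and 0.02 and were led by HLA-DMA, CIITA and HLA-DRA, at 1.36, 1.31 and 1.28 (0.25, 0.24 and 0.25). Iron homeostasis genes (21, adjusted p = 0.750, and 0.111) had medians of 0.21, −0.15 and −0.07 and were led by STEAP3, ACO1 and HMOX1, at −1.04, −0.94 and 0.83 (−0.39, −0.15 and −0.18).

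Hypoxia and glycolysis genes (31, adjusted p = 0.0782, and 0.606 without the 1205Lu pair) had medians of −0.69, −0.02 and 0.04, with CA12, ANGPTL4 and LOX at −2.04, −1.59 and −1.37 (−0.76, −0.37 and −0.19). Unfolded protein and amino acid stress genes (27, adjusted p = 0.207, and 0.155) had medians of 0.11, 0.14 and −0.03, with PHGDH, SLC7A11 and DNAJC3 at 1.29, 0.98 and −0.91 (0.54, 0.05 and −0.38). WNT target genes (14, adjusted p = 0.207, and 0.111) had medians of −1.50, 0.21 and 0.11, with SP5, AXIN2 and DKK1 at −1.46, −1.42 and 1.34 (−1.46, −0.66 and 0.61). Cancer-testis antigens (10, adjusted p = 0.0587, and 0.137) had medians of 1.90, 0.31 and 0.03, with MAGEA3, CSAG1 and MAGEA12 at 2.29, 2.07 and 1.92 (0.75, 0.65 and 0.47), genes of 1 cluster with similar sequences. Ribosomal protein genes (40, adjusted p = 0.817, and 0.313) had medians of −0.05, −0.10 and 0.17, with RPS6, RPS13 and RPS20 at −0.40, −0.34 and −0.32 (−0.10, −0.08 and −0.03). Neural crest genes (16, adjusted p = 0.817, and 0.594) and NOTCH target genes (11, adjusted p = 0.441, and 0.451) lay inside their random lists in every line.

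Over all genes tested, 0 members of any list passed edgeR. Adjusted over the list alone, 1 NF-kB target (TRAF1, adjusted p = 0.0416) and 1 keratinocyte marker (DSP, adjusted p = 0.0225) passed, and 0 members of every other list did. Camera called 3 of 32 lists higher and 7 lower on 3 pairs, and 5 and 4 of 30 on the WM983B and WM1341D pairs, of which 3 had the same direction in both fits. With an estimated correlation, and with fry, 0 lists were called. These forms had too few residual degrees of freedom to decide, and the preset correlation does not measure variation between cultures. The list results thus stay open.

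**Figure D3:**
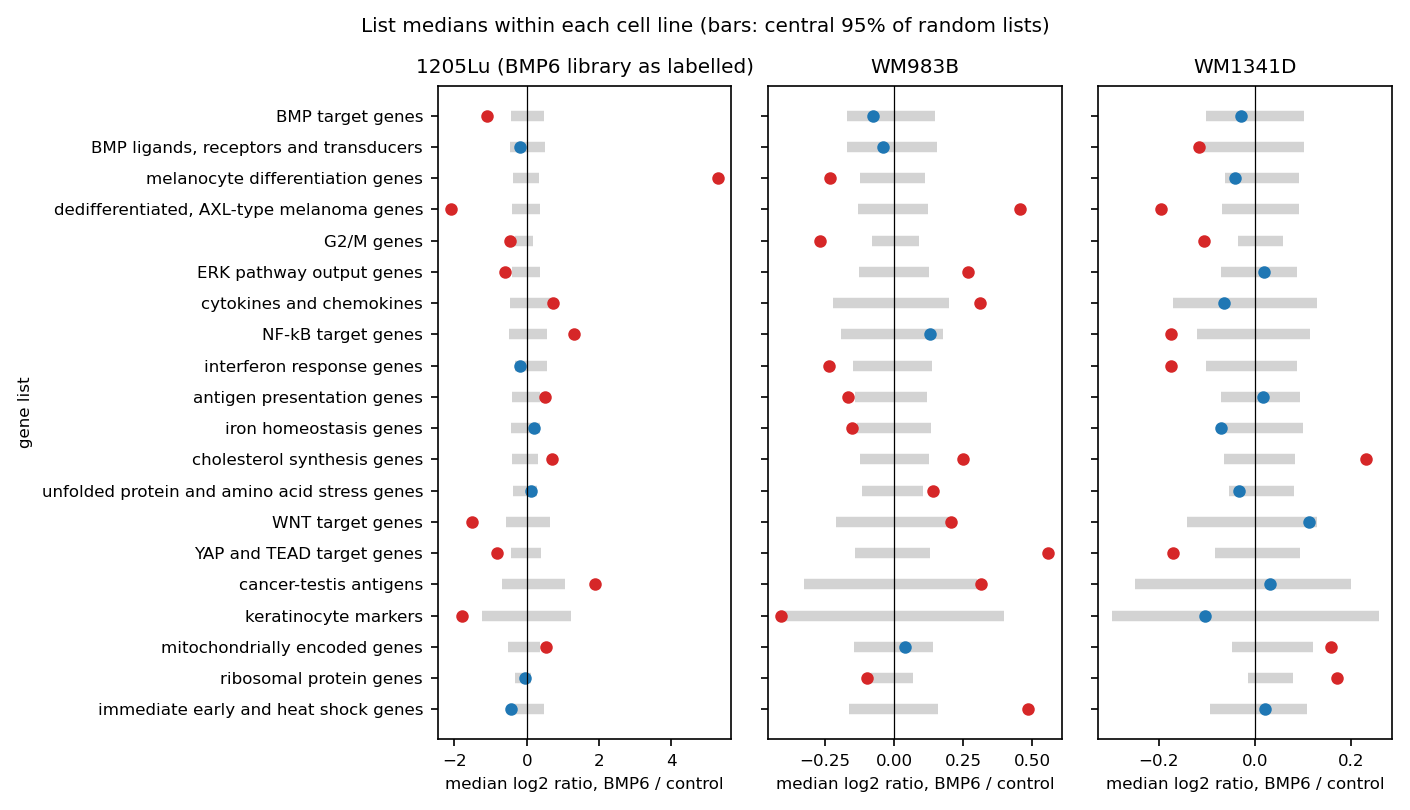
Median log2 ratio of BMP6 over control for 20 gene lists in each cell line (points), with the central 95% of 10000 matched random lists as grey bars and points outside them in red. The cholesterol synthesis genes lie above and the G2/M genes below their bars in all 3 lines, and each panel has its own horizontal scale.

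Within 1205Lu, 26 of the 29 melanocyte differentiation genes were at least 2-fold higher in the library labelled 1205Lu BMP6 by the size rule, 0 were 2-fold lower and 1 was lower by less. Of the genes with the largest ratios, SLC24A5, a pigment cell ion exchanger, had 993 counts against 0, which makes it at least 303-fold higher. BIRC7, TRIM63, TRPM1, MBP and GPR143 had log2 ratios between 8.90 and 9.29. NPTX2 had 11 counts against 20521 and SOX9 10 against 16059, with log2 ratios of −10.77 and −10.54. GABBR2, ST8SIA5 and TSPAN18 had log2 ratios of −10.09, −10.03 and −9.75. By size, 1556 genes were at least 2-fold higher and 2029 lower of 11772 that reached 5 CPM, or 30.5%. Scaling to library size gave 2062 higher and 1618 lower, so which direction was the more frequent followed the scaling, and with no minimum of CPM there were 3575 higher and 2955 lower.

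Within WM983B, CCDC144NL-AS1 had 299 counts in the BMP6 library against 11, a 25.6-fold difference with a counting interval of 14.1 to 51.8. The cadherin FAT3 had 451 against 27 counts, TP53I11 had 1097 against 76 and OLFML2A had 1190 against 109, with log2 ratios of 3.87, 3.72 and 3.33, and TMEM178B had 3.17. THNSL2 was at 9 counts against 227 (log2 ratio −4.42) and ZC3HAV1L at 11 against 172 (−3.79). The protease inhibitor TFPI2 had 73 against 697 counts, the globin CYGB 180 against 1502, SLAMF7 32 against 279 and FAM83G 20 against 178, with log2 ratios of −3.30, −3.13, −3.12 and −3.10. By size, 121 genes were higher and 160 lower of 11139 at 5 CPM or more, or 2.52%. With 1 library per condition no gene was tested within the line.

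Within WM1341D fewer genes differed. MRGPRX3 had 2578 counts against 253, an 11.3-fold difference in the BMP6 library with a counting interval of 9.92 to 12.9. The mechanosensitive channel PIEZO2 had 299 against 118 counts (log2 ratio 1.47) and the RNA-binding protein MSI1 134 against 57 (1.35), and FERMT1 and C1QL1 had log2 ratios of 1.34 and 1.33. The adhesion molecule NRCAM had 5 counts against 346 and the kinase DGKI 9 against 419, with log2 ratios of −5.52 and −5.13. BAALC had 8 against 163 counts, the fatty acid transporter CD36 45 against 742, PCDHGC3 29 against 392 and PXDN 36 against 343, with log2 ratios of −3.92, −3.84, −3.53 and −3.04, and PCDHGC3 shares exons with its gene cluster. By size, 13 genes were higher and 51 lower of 10924 at 5 CPM or more, or 0.586%.

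Few genes differed at least 2-fold in the same direction in both WM lines. BMP6 was the 1 gene higher in both, where independence of the lines gives 0.0378, but its overexpression was set by the design. No other gene was higher in both. MYEOV, DNAJA4, NIBAN1, CASP1, DSP and SLAMF7 were the 6 lower in both, where independence gives 0.271. DNAJA4, a heat shock co-chaperone, had log2 ratios of −1.14 and −1.25, and the protease CASP1 had −1.73 and −1.04. NRCAM, DGKI and MGAM were the 3 that were higher in WM983B and lower in WM1341D, where independence gives 0.265. DNAJA4, CASP1 and MGAM fall outside the naming rule and were chosen after their values were seen. Across 10320 genes, BMP6 included, the log2 ratios of WM983B and WM1341D had a Pearson r of 0.101 and a Spearman rho of 0.0133. BMP6 lies far out at 8.03 and 7.56, where the SD of the ratios was 0.403 and 0.254. It thus raises this r, which was not computed without it.

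The 1205Lu ratios hardly correlated with the others either. Pearson r was 0.0710 with WM983B over 10940 genes and 0.00191 with WM1341D over 10551, with Spearman rho of 0.0213 and 0.0489. Against WM983B, 43 genes were higher and 64 lower in both by size, where independence gives 16.0 and 13.4, and against WM1341D 1 and 20, where it gives 0.944 and 5.06. Opposite directions also exceeded independence: 26 genes were higher in 1205Lu and lower in WM983B and 34 the reverse, where it gives 15 and 14.2, and 9 and 5 against WM1341D, where it gives 4.37 and 1.09. These correlations run across genes, which are not independent replicates. The 1205Lu and WM983B pairs may not be independent either, since their BMP6 libraries had a Pearson correlation of 0.991.

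**Figure D4:**
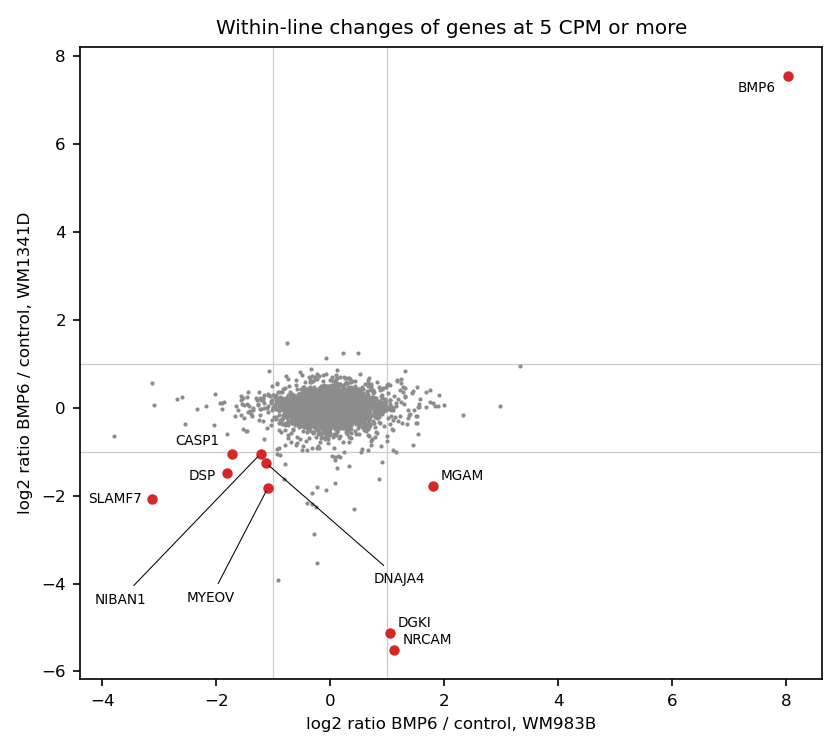
Log2 ratio of BMP6 over control in WM983B (horizontal) and in WM1341D (vertical) for 10312 genes that reach 5 CPM in both lines, 1 point per gene, without genes of the Y chromosome and XIST. Red points are the genes at least 2-fold different in both lines, with BMP6 at 8.03 and 7.56, and grey lines mark a 2-fold difference.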

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

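The tests of WM983B cells under the 1205Lu BMP6 label, of a mixture of cells and of scaling were chosen after the result was seen, whereas the test of a response of 1205Lu cells, the test of counting noise and the splits of the libraries were written before.

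The library labelled 1205Lu BMP6 is closer to the WM983B libraries than to the 1205Lu control, and of 281 genes that differ 2-fold within the WM983B pair, 255 (90.7%) lie closer to WM983B BMP6 in it. The tables argue against scaling or depth, since the rank correlation of TPM is higher by at least 0.138 with the WM983B libraries, and against a mixture of 1205Lu and WM983B cells, since 89 genes private to the 1205Lu control keep a median of 0.641% of their level (0.669% in WM983B BMP6). A culture or library of WM983B cells under this label is consistent with 16 of 16 genes private to WM983B lying within 2-fold of WM983B BMP6, at a median difference of 0.0835 (log2), but not as the same library under both names, which differ by a chi-square of 19.0 per degree of freedom over 10537 genes. The tables also argue against a response of 1205Lu cells to BMP6 as the whole cause, by the bound set in advance: 6 genes in runs of neighbours at the floor of the 1205Lu control reach 5 CPM here, although these are families of related genes (ZNF441 and ZNF440, and MAGEA6, MAGEA12, CSAG1 and MAGEA3) that might be silenced together, and all but ZNF441 keep 3 or 4 counts in the control. The identity of the cells was not tested apart from expression, and a response to BMP6 beside a difference in cells stays open. The 1205Lu ratios thus set a WM983B-like profile against a 1205Lu profile. They cannot be read as an effect of BMP6.

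The 6 libraries make 10 splits into groups of 3, the real one included, too few for a share under 0.05. The real split called 0 genes, so that all 10 call at least as many by construction and the count decides nothing, and the highest other called 6926. That number came from the splits that part the 1205Lu pair alone, which points to a structure among the samples, and the other splits that part all 3 pairs, as the real one does, called 0 each.

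The changes of WM983B and WM1341D hardly correlate across genes. Counting noise of low genes is argued against by a Pearson r of −0.0357 over the 3580 genes at 50 CPM or more in all 4 WM libraries. Differences in the response of the cell lines, or between the single cultures sampled, stay open and were not tested.

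Some lists had medians outside their random lists in opposite directions in a pair of cell lines, and the differences were not tested. The median log2 ratio in 1205Lu minus that in WM983B was 5.52 for melanocyte differentiation genes, −2.55 for dedifferentiated, AXL-type genes, −0.85 for ERK pathway output genes, 0.67 for antigen presentation genes, −1.71 for WNT target genes and −1.38 for YAP and TEAD target genes. For NF-kB target genes 1205Lu minus WM1341D was 1.49. WM983B minus WM1341D was 0.65 for dedifferentiated, AXL-type genes, 0.73 for YAP and TEAD target genes and −0.27 for ribosomal protein genes. Among single genes that were 2-fold higher in WM983B and 2-fold lower in WM1341D, the same difference was 6.64 for NRCAM, 6.17 for DGKI and 3.57 for MGAM.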

How the results depend on the processing

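The runs without the 1205Lu pair in DESeq2, in limma-voom and with an estimated correlation were chosen after the data were seen, and the other alternatives before. The counts of genes called across the 3 lines, 0 higher and 0 lower in edgeR, were also 0 without the cell-line pairing, with other scalings or filters, in limma-voom and on TPM. DESeq2 called 3 higher and 15 lower, and without the 1205Lu pair 8 and 20, where limma-voom called 1 and 0. Leaving out single pairs gave 0 to 1 higher and 0 lower. The log2 fold change of BMP6, 6.37, passed the threshold in DESeq2 at 6.54, and without the 1205Lu pair at 7.93 in DESeq2 and 7.90 in limma-voom. It was 4.67 without the pairing and ranged from 5.07 to 7.92 when single pairs were left out, passing without the 1205Lu pair alone. Camera called 3 lists higher and 7 lower, but 0 and 0 with an estimated correlation, with fry, and with an estimated correlation without the 1205Lu pair, and 4 to 5 higher and 4 to 12 lower when single pairs were left out. The cause was not tested, but an estimated correlation and fry could hardly call a list at these few residual degrees of freedom. Without the 1205Lu pair 12 of 30 lists turned direction, and ERK output genes (adjusted p = 0.0195) and YAP and TEAD targets (0.0316) passed as higher. Of the lists followed through the alternatives, those called across the 3 lines and the BMP lists, 4 turned, with adjusted p of 0.982 for TGF-beta targets (8.37e-05 to 0.982 over the pairs left out), 0.0119 for melanocyte genes (1.32e-11 to 0.0119), 0.313 for AXL-type genes (1.50e-07 to 0.313) and 0.461 for BMP antagonists (0.0102 to 0.461). With an estimated correlation as well these were 0.984, 0.820, 0.853 and 0.820. BMP ligands, receptors and transducers turned without the WM1341D pair, at 0.973 (0.348 to 0.973). Over all alternatives for the lists followed, 64 values kept the side of the threshold, 41 lost it, of which 10 are of the mixed form of fry, which has no direction, 9 reversed and 2 came to pass. For the 24 genes named across the cell lines by the same direction in all 3, and for no other named gene, 322 values kept direction and side of the threshold and 14 came to pass. For list medians outside their random lists within a cell line, 157 of 184 values under alternatives differed from the median by less than 1 SD of random lists and 27 by more. The Pearson r of WM983B and WM1341D, 0.101, was between 0.0791 and 0.106 with another prior count, a minimum of 1 CPM or TPM, each with BMP6 included. A minimum of 1 CPM, or none, admits more genes to the size rule by construction: 2508 and 3575 higher and 2613 and 2955 lower in 1205Lu, where the more frequent direction turned with no minimum, 302 and 627 higher and 417 and 725 lower in WM983B, and 46 and 268 higher and 212 and 704 lower in WM1341D. Ratios of TPM plus 1 left 4 genes higher in WM1341D. Scaling to library size moved the 1205Lu median of all genes by 0.197 (log2) and gave 2062 genes higher and 1618 lower there. With 1 library per condition and line, the depth limits low genes: a count of 0 allows up to 0.0938 to 0.122 CPM.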

Other observations

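The tests of the 9p21 pattern below were all chosen after the result was seen.

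In the WM983B and WM1341D pairs alone, DESeq2 called genes that edgeR did not, and those named here, CXCL8 apart, are outside the naming rule and were chosen after their values were seen. The inflammasome adaptor PYCARD had a log2 fold change of −0.94 (adjusted p = 0.0331) and BST2, an interferon-induced membrane protein, had −0.72 (adjusted p = 0.0469). DNAJA4 had −1.19, RPH3A −2.44, ENTHD1 −2.49 and the collagen COL12A1 −1.02. On the higher side CXCL8 had 1.45, FXYD5 1.00 and the secreted WNT regulator SFRP1 0.78. The members of the BMP target list outside the naming rule included the inhibitory SMADs, with 1055 against 995 counts of SMAD6 in WM983B and 160 against 242 in WM1341D, and 254 against 237 counts of SMAD7 in WM983B and 460 against 527 in WM1341D.

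The tumour suppressor genes CDKN2A and CDKN2B had 4 and 3 counts in the 1205Lu control and 2637 and 210 in the library labelled 1205Lu BMP6, where WM983B BMP6 had 3635 and 370. Their neighbour MTAP had 5127 counts in the 1205Lu control and 1326 in that library.

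Genes of chromosome 9p21 are lower together in the WM1341D BMP6 library than in its control, with 12 against 66 counts of MTAP, 8 against 41 of FOCAD and 9 against 52 of KLHL9, and 12 of 15 tested genes between MLLT3 and ELAVL2 lower. The tables argue against 1205Lu cells or reads in the WM1341D control as the whole cause, since abundant 1205Lu genes that are under 1 CPM in WM1341D BMP6 reach there a median of 0.475% of their 1205Lu level (35 genes, quartiles 0.171 to 1.04), where the summed drop of the segment needs 1.58% (counting limits 1.29 to 1.86), and against WM983B cells or reads, whose genes reach 0.441% (9 genes, quartiles 0.147 to 1.44) where 2.33% is needed (1.90 to 2.76). Earlier forms of both tests, over genes private to the line (medians 0.0956% and 0.760%) and with fixed bounds on the same medians, did not decide. For fewer cells that keep the segment, the lowest run of 5 neighbouring genes there lies at −1.98 and first of 17528, but at a difference of only −0.17 from the lowest run elsewhere, with a counting SE of 0.56. Fewer such cells and lower expression of the segment cannot be told apart at these counts.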
